A study of Mus musculus with 10 samples.

How the data were processed

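The data were RNA-seq measurements of kidney glomeruli, the filtering units of the kidney, from the mouse, with 10 libraries in 2 groups. The wild-type group and the group carrying the Col4a3 missense variant p.G799R held 5 libraries each, and each library took its group and replicate number from its own label. The zygosity, age, sex, litter and strain of the mice and the way the glomeruli were isolated are not given in the sources used here. The labels do not say whether the 5 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, RNA was extracted with TRIzol and enriched mRNA was fragmented and made into cDNA libraries with a NEBNext Ultra kit.

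The authors deposited 1 table of FPKM values, which are fragment counts scaled for transcript length and library total, for 22053 Ensembl gene identifiers. Per the submitters' processing notes, fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM were used. These notes give no role or order for the tools, and the genome build and annotation are not given in the sources used here. FPKM is a relative unit, so RNA from 1 cell type that takes a larger share lowers the values of the genes of the others. Each column was matched to its library through the column name that the library's own label states, and 0 columns belonged to other samples. Symbols were found for 21963 identifiers. Where 2 identifiers shared a symbol, the one with the lower mean kept its identifier in its name. Chromosome positions were looked up by identifier in GENCODE M21, which uses the mouse build GRCm38, and may differ from the authors' build. The annotation had no entry for 90 identifiers.

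FPKM values give no total count, so absolute depth is unknown and no counting interval was computed. Low values move in steps of what 1 fragment is worth, which differs between libraries with their depth. From the commonest ratio between libraries among genes under 0.3 FPKM, relative depth was estimated at 0.860 to 1.19 times that of wild-type library 1, a range of 1.39-fold. The mean was 1.09 for wild type and 0.927 for G799R. In each library only 41 to 60 of the 599 to 695 low genes compared lay at that ratio, so these depths are estimates. Simulated libraries of 4000 genes gave relative depth back with an error of at most 0.235%.

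FPKM was used as deposited and transformed to log2(FPKM + 1). The pseudocount of 1 understates changes of low genes, and every log2 difference is G799R minus wild type on this scale, while folds are ratios of mean FPKM. The 13117 genes with a mean of at least 0.5 FPKM were tested with limma-trend (limma 3.58.1 in R 4.3.3), a moderated two-sided test, with Benjamini-Hochberg adjustment and a threshold of 0.05. A count model was not used, since FPKM values are not counts. The 30 gene lists, the rule for named genes and the alternatives named below as set beforehand were all fixed before the data were examined. Of the lists, 29 had at least 5 tested genes, and the list of mitochondrially encoded genes had 4 and was not tested. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 29 lists, and again with an estimated correlation. The score of a list in a library is the mean log2(FPKM + 1) of its members. The tubule score pools the proximal tubule list with the list of distal tubule and collecting duct. The glomerular score pools the podocyte, endothelial and mesangial lists. Score differences were tested with an exact two-sided permutation test, for which 5 against 5 libraries allow no p below 0.0079. Within-group correlations used deviations from the group means over 10 libraries and 100000 permutations within groups.

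The rule for named genes took Col4a1 to Col4a6, and Hspa5, Ddit3, Atf4, Xbp1 and Nphs1 whatever their values. It also took the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 FPKM and no overlap between groups, leaving out predicted and clone names. From each list it took up to 4 members with the smallest p. Some genes taken by this rule are not reported here and were not replaced. On simulated data built from the 13117 tested genes of this comparison, the test recovered 44.8% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 8 false calls among 155. A raised list was found and 0 of 20 unchanged lists were called. The simulated noise was drawn independently for each gene, and few genes were changed. The simulation therefore does not show how the tests do on lists of correlated genes or when most genes shift. Alternatives set beforehand were pseudocounts of 0.1 and 0.5, no filter and a filter of 2 FPKM, median-of-ratios scaling, quantile normalisation, other limma settings, a replicate block, the tubule score as a covariate and leaving out each library. Alternatives chosen after seeing the data were glomerular marker scaling and leaving out G799R libraries 3 and 4, alone or with wild-type library 1. Glomerular marker scaling sets the glomerular score equal in every library. The pseudocount was added after it, so it shifts low genes less than high ones. Camera calls under it can therefore depend on expression level. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.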

Results

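Gene expression was measured by RNA-seq in kidney glomeruli of 5 wild-type libraries and 5 libraries from mice with the p.G799R change in Col4a3, the gene of the alpha 3 chain of type IV collagen. This chain forms, with the chains of Col4a4 and Col4a5, the collagen network of the glomerular basement membrane. The design text states the comparison of the mutant with the wild type. The series title also names tauroursodeoxycholic acid, a bile acid, and no treated samples were analysed here. FPKM sums ran from 320720 to 340875 per library, and absolute depth is unknown. The Y-linked gene Ddx3y was expressed in every library.

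Col4a3 mRNA was higher in G799R glomeruli, at 213 ± 12.4 FPKM against 138 ± 13.6 (SD, n = 5 each), with every G799R library above every wild-type library. The gene has the identifier ENSMUSG00000079465. The log2 difference was 0.63 ± 0.08 (SE), with a limma adjusted p of 6.2e-05. The variant is a missense change, so the mRNA level does not check the labels. Col4a3 lies on chromosome 1 at 82586921 to 82722059, next to Col4a4. Col4a4 and Col4a5 were 1.46-fold and 1.47-fold higher. Col4a6, a chain of other basement membranes, was 1.75-fold higher at 4.86 FPKM. Col4a1 and Col4a2, which make the collagen network of most basement membranes, rose further, by 3.21-fold (390 ± 108 against 121 ± 39.4 FPKM) and 2.69-fold (160 ± 47.2 against 59.4 ± 16.1 FPKM). Their adjusted p-values were 0.00026 and 0.00063. All 6 chains were called higher in FPKM as deposited, and the tubule score of the same G799R libraries was lower by 2.35 on the log2 scale. With the glomerular score set equal in every library, Col4a1 and Col4a2 stayed higher, at log2 differences of 1.05 and 0.78. Under that scaling Col4a3, Col4a4 and Col4a5 turned to −0.0017, −0.09 and −0.08 and Col4a6 stood at 0.13, and none of these 4 was called.

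**Figure D1:**
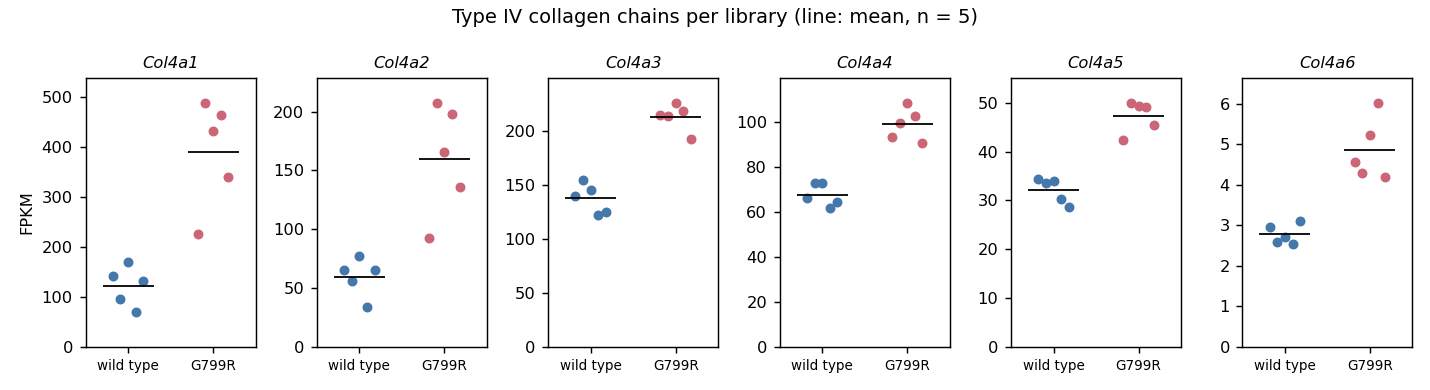
FPKM (linear axes from 0) of the 6 type IV collagen genes in each of the 5 wild-type (blue) and 5 G799R (red) libraries, with the group mean as a line. The groups do not overlap for any of the 6 genes in FPKM as deposited, and under glomerular marker scaling Col4a3 (log2 difference −0.0017), Col4a4 and Col4a5 change sign.

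Markers of tubule cells, which surround the glomeruli in the kidney, were far lower in the G799R libraries. All 34 proximal tubule markers fell, with a median log2 difference of −2.82, and 28 of 29 markers of distal tubule and collecting duct fell, with a median of −2.00. The receptor gene Cubn was 9.55-fold lower and Egf, a product of the distal tubule, 3.44-fold lower. Both lists were called lower by camera (adjusted p = 1.2e-24 and 1.7e-15), but not with an estimated correlation, where both had adjusted p = 0.31. The tubule score was 6.14 ± 0.30 in wild type and 3.79 ± 0.36 in G799R (SD, n = 5 each). This difference of −2.35 had an exact permutation p of 0.0079, the smallest possible. Genes of these lists made up 4.07% to 6.64% of all FPKM in wild-type libraries and 0.594% to 1.17% in G799R libraries.

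Markers of the 3 cell types of the glomerular tuft were higher in G799R. Of 34 podocyte markers 33 rose (34 adjusted over the list alone), with a median log2 difference of 0.68. Nphs1, which encodes the slit diaphragm protein nephrin, was higher by a log2 difference of 0.65. Of 30 endothelial markers 24 rose and 1 fell (26 and 1 adjusted over the list alone), with a median of 0.70 and Plvap 2.25-fold higher. Of 24 mesangial and smooth muscle markers 15 rose (15 adjusted over the list alone), with a median of 0.69, among them the receptor gene Pdgfrb (2.21-fold) and the renin gene Ren1 (2.05-fold). With the glomerular score set equal, which removes the common rise of these lists by construction, 5, 7 and 5 members were higher and 2, 3 and 3 lower. Camera gave adjusted p-values of 4.7e-09, 5.4e-04 and 0.0252 as deposited. With an estimated correlation these became adjusted p = 0.40, 0.56 and 0.57, and without G799R libraries 3 and 4 the mesangial list was no longer called (adjusted p = 0.0757). The tubule score was lower in these same libraries, and the endothelial score rose by 0.0276 less than the podocyte score (exact permutation p = 0.83). Of 18 genes linked to podocyte injury 13 rose (14 adjusted over the list alone), with a median of 0.69, an adjusted p of 0.0028 and adjusted p = 0.56 with an estimated correlation, and under glomerular marker scaling 3 were higher and 0 lower by limma. The camera call against all genes, whose median was negative under that scaling, then held with an estimated correlation (adjusted p = 0.0271), while relative to the glomerular score the list score differed by 0.04 (exact permutation p = 0.44). Among them Cdkn1a, a cell cycle inhibitor, rose 3.17-fold.

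**Figure D2:**
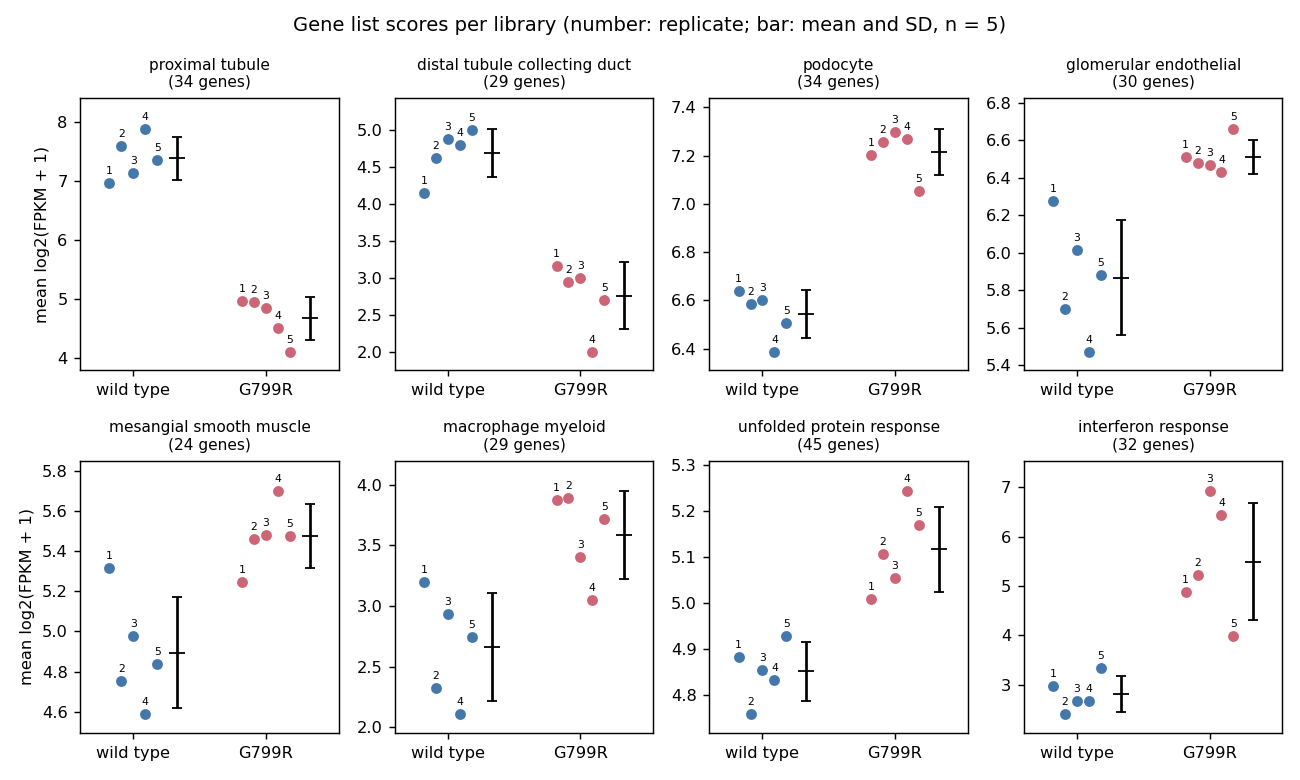
Mean log2(FPKM + 1) of 8 gene lists in each library, for wild type (blue) and G799R (red), with replicate numbers beside the points, bars showing group mean and SD (n = 5), and axes that do not start at 0. Both tubule lists lie lower in every G799R library, the interferon response scores are higher (SD 1.19 against 0.36), and the higher unfolded protein response turns to a median of −0.32 under glomerular marker scaling. The median of all genes under that scaling is −0.38.

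Across all genes, 7845 of the 13117 tested were called by limma, with 5308 higher and 2537 lower in G799R (8452 genes had an unadjusted p under 0.05). At least 2-fold changes on the log2(FPKM + 1) scale were found in 420 genes that rose and 1065 that fell. The groups did not overlap for 41.8% of tested genes, where chance gives 0.794%. The first principal component held 75.1% of the variance and separated the groups. The median log2 difference of all genes was 0.17. The share of calls that were higher depended on scaling, at 67.7% as deposited, 47.8% under median-of-ratios scaling (3057 higher, 3341 lower; median of all genes 0.02) and 7.26% under glomerular marker scaling (628 higher, 8027 lower; median −0.38). With the tubule score as a covariate 0 genes were called by limma (707 at an unadjusted p under 0.05). That score nearly follows genotype, and the median SE of the genotype term rose from 0.11 to 0.42.

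The 10 largest falls included enzymes and transporters. Miox, which starts inositol breakdown, fell from 525 ± 139 to 44.0 ± 18.0 FPKM (adjusted p = 4.4e-06). Nox4, a source of reactive oxygen species, was 12.5-fold lower, and the lactate transporter gene Slc5a12 11.6-fold lower. Ttr, Hsd3b3 and Hpd were 15.6-fold, 18.3-fold and 15.5-fold lower. Klk1, Ugt1a10, Cyp4a10 and Cyp4a14 were also among the 10 largest falls. Each of these has close paralogs, and reads shared with them make the values uncertain. Cyp4a14 was at 1.22 FPKM in wild-type library 1 and at 59.2 to 140 FPKM in the other 4. The tubule score was lower in the same G799R libraries.

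Genes of the interferon response, an antiviral and inflammatory program, showed the largest rises. All 32 tested members rose, also when adjusted over the list alone, with a median log2 difference of 2.73. Camera gave an adjusted p of 4.3e-07, and adjusted p = 0.56 with an estimated correlation. Irf7, a transcription factor of this response, rose from 6.02 ± 2.59 to 267 ± 314 FPKM (adjusted p = 0.00081), and Isg15, a ubiquitin-like protein, from 3.54 ± 2.47 to 85.4 ± 84.6 FPKM. Psmb8 and Psmb9, subunits of the immunoproteasome, were 6.14-fold and 7.19-fold higher, and Irf1 and Irf9 3.29-fold and 3.81-fold higher. Of the 10 largest rises, Gbp2b, Tgtp1, Mndal, Ifi27l2a, Irf7, Tgtp2, Ifi44l, Isg15 and Gbp3 are known to be induced by interferon. Tgtp1 and Tgtp2, Mndal, Gbp2b and Gbp3, and Klk1b22, the remaining gene, have close paralogs, so their single values are uncertain. The spread between G799R libraries was wide. Irf7 stood at 768 FPKM in G799R library 3, 384 in library 4, 73.4 and 89.6 in libraries 1 and 2 and 20.1 in library 5, and at 3.83 to 10.2 in wild type. Under glomerular marker scaling 31 of the 32 members were still called higher, with a median of 2.15, and all 32 were called without G799R libraries 3 and 4.

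Of 29 macrophage and myeloid markers 18 rose (18 adjusted over the list alone), with a median log2 difference of 0.88, an adjusted p of 0.0053 and adjusted p = 0.57 with an estimated correlation. Of these markers 7 were higher and 0 lower by limma under glomerular marker scaling, with a median of 0.35, and relative to the glomerular score the list score differed by 0.29 (exact permutation p = 0.23). Ctss, a lysosomal protease, was 3.29-fold higher and the Fc receptor subunit gene Fcer1g 5.64-fold higher. Of 34 genes of inflammation and chemokines 18 rose (18 adjusted over the list alone), with a median of 0.73, an adjusted p of 0.0022 and adjusted p = 0.56 with an estimated correlation. Of these genes 9 were higher and 3 lower under glomerular marker scaling, with a median of 0.26, and relative to the glomerular score the list score differed by 0.155 (exact permutation p = 0.37). Tnfrsf1a, a receptor of tumour necrosis factor, was 2.31-fold higher and the chemokine gene Cx3cl1 2.17-fold higher. Of 17 complement genes 9 rose and 3 fell, and the list was not called (adjusted p = 0.17). C1ra and C1s1, proteases that start the classical pathway, rose 2.84-fold and 3.09-fold, while C3, the central component, was lower by a log2 difference of −1.16 ± 0.33 (SE; adjusted p = 0.0104). The list was called with no filter and under median-of-ratios scaling (medians 0.52 and 0.66), in both cases not with an estimated correlation. It was also called higher than other genes under glomerular marker scaling (median 0.22, 6 higher and 4 lower, adjusted p = 1.9e-06), there also with an estimated correlation (adjusted p = 0.0288). Relative to the glomerular score, however, the list score differed by −0.15 (exact permutation p = 0.17). C3 falls outside the naming rule and was chosen after its values were seen. Among 14 lymphocyte genes 1 rose (Gzmb) and 1 fell (Cd79a), and the list was not called (adjusted p = 0.70), with a median of 0.11. Under glomerular marker scaling the median turned to −0.17, with 1 member higher and 3 lower. That median lies above the one of all genes. Camera called the list higher than other genes (adjusted p = 0.0315), but not with an estimated correlation (adjusted p = 0.36). Low genes shift less under that scaling, and the lymphocyte list had a wild-type score of only 1.33. The lower tubule score accompanied all of these lists.

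Genes of the unfolded protein response, which adjusts protein folding in the endoplasmic reticulum, rose by a small amount in FPKM as deposited. Most of them were lower under glomerular marker scaling, as were most tested genes. Of 45 members 27 rose and 2 fell (27 and 2 adjusted over the list alone), with a median log2 difference of 0.27. The list was called higher by camera (adjusted p = 0.0160), but not with an estimated correlation (adjusted p = 0.56), nor under median-of-ratios scaling (median 0.09) or quantile normalisation (median 0.19). Under glomerular marker scaling 2 members were higher and 28 lower, with a median of −0.32. Of all 13117 tested genes 8027 were called lower under that scaling, and their median was −0.38. Camera did not call the list apart from other genes there (adjusted p = 0.83). The chaperone gene Hspa5 went from 215 ± 35.3 to 317 ± 96.6 FPKM (log2 difference 0.52 ± 0.19 SE, adjusted p = 0.0324), with overlapping groups, and −0.11 under glomerular marker scaling. Its call was lost when any 1 of wild-type libraries 2 and 3 or G799R libraries 2, 4 and 5 was left out (log2 differences 0.37 to 0.54, adjusted p 0.050 to 0.080). The call was also lost with no filter (0.52, adjusted p = 0.0534), under median-of-ratios scaling (0.35, adjusted p = 0.16), under quantile normalisation (0.44, adjusted p = 0.0514) and without G799R libraries 3 and 4 (0.40, adjusted p = 0.0736). Ddit3, which encodes the stress factor CHOP, and the transcription factor gene Xbp1 were 1.31-fold and 1.37-fold higher, were not called under median-of-ratios scaling, and turned to log2 differences of −0.23 and −0.19 under glomerular marker scaling. Atf4, which acts in the same response, was at 70.6 ± 5.89 and 76.4 ± 5.40 FPKM and was not called (adjusted p = 0.21), while under glomerular marker scaling it was called lower (−0.51). Casp12, a caspase of the endoplasmic reticulum, rose 2.39-fold, whereas Herpud1, which acts in the degradation of misfolded proteins, was 1.91-fold lower. The tubule score was lower in these G799R libraries.

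**Figure D3:**
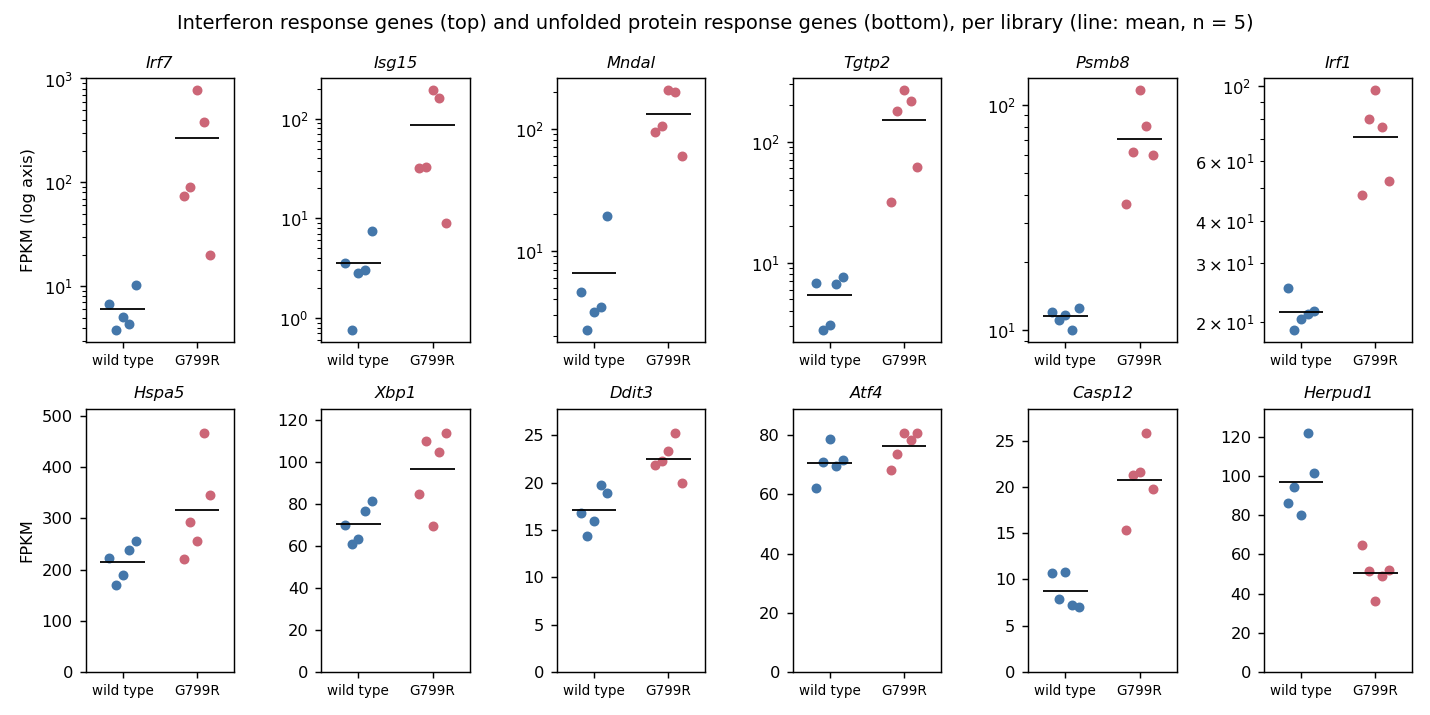
FPKM of 6 interferon response genes (top, log axes) and 6 unfolded protein response genes (bottom, linear axes from 0) in each of 5 wild-type (blue) and 5 G799R (red) libraries, with group means as lines; Irf7 ranges from 20.1 to 768 FPKM among G799R libraries. Hspa5, Xbp1 and Ddit3 are higher as deposited and have log2 differences of −0.11, −0.19 and −0.23 under glomerular marker scaling. The median of all genes under that scaling is −0.38.

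Genes that modify and fold collagen were higher in G799R as deposited, with 16 of 22 called (16 adjusted over the list alone) and a median log2 difference of 0.42, which turned to −0.15 under glomerular marker scaling (3 higher, 6 lower; score relative to the glomerular score −0.15, exact permutation p = 0.0397). The list had an adjusted p of 0.0016, and adjusted p = 0.56 with an estimated correlation. Under glomerular marker scaling camera called it higher than other genes (adjusted p = 0.0053), but not with an estimated correlation (adjusted p = 0.26). Plod2, a lysyl hydroxylase, was 2.24-fold higher and Crtap, a part of the prolyl 3-hydroxylase complex, 1.80-fold higher. Of 28 basement membrane genes 18 rose and 5 fell (18 and 6 adjusted over the list alone). Their median was 0.57 as deposited, where the list was not called (adjusted p = 0.0675). Under glomerular marker scaling the median was −0.02 with 4 members higher and 8 lower, and camera, which compares a list with all other genes, called it higher than these (adjusted p = 2.8e-04; adjusted p = 0.13 with an estimated correlation). Relative to the glomerular score the list score was lower by 0.2960 (exact permutation p = 0.0079). The laminin chain gene Lama2 rose 4.13-fold to 2.90 FPKM and Tinag was 7.09-fold lower. Of 17 collagen receptor genes 14 rose and 2 fell (14 and 2 adjusted over the list alone), with a median of 0.59, an adjusted p of 0.0051 and adjusted p = 0.56 with an estimated correlation. Glomerular marker scaling left 4 of them higher and 3 lower, with a median of 0.01 and a score relative to the glomerular score of −0.15 (exact permutation p = 0.0317). Camera then called these receptor genes higher than other genes (adjusted p = 2.2e-04), but not with an estimated correlation (adjusted p = 0.11). Of 42 genes of interstitial matrix and fibrosis 30 rose and 1 fell (30 and 1 adjusted over the list alone), with a median of 0.64, an adjusted p of 9.9e-04 and adjusted p = 0.56 with an estimated correlation. The same scaling left 9 higher and 1 lower, with a median of 0.12 and adjusted p = 0.0271 with an estimated correlation, and relative to the glomerular score the list score differed by −0.0091 (exact permutation p = 0.86). Col1a2, a chain of type I collagen, was 2.83-fold higher. All of these differences came with the lower tubule score.

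Metabolic genes were lower in G799R. All 45 oxidative phosphorylation genes fell, with a median log2 difference of −0.85, and 27 of 31 genes of fatty acid oxidation fell while 1 rose, with a median of −0.89. Camera gave adjusted p-values of 4.5e-24 and 1.8e-15, and adjusted p = 0.31 and 0.28 with an estimated correlation. Ndufs1, of respiratory complex I, was 2.12-fold lower, and Ppara, a regulator of fatty acid oxidation, 4.86-fold lower. Of 14 genes of bile acid receptors and transport 11 fell and 1 rose, with a median of −1.62, an adjusted p of 1.1e-05 and adjusted p = 0.28 with an estimated correlation. Nr1h4, the bile acid receptor FXR, fell from 28.2 ± 8.59 to 4.44 ± 1.22 FPKM (adjusted p = 4.0e-06). Of 25 cholesterol synthesis genes 12 fell and 2 rose, with a median of −0.15, an adjusted p of 0.0010 and adjusted p = 0.56 with an estimated correlation. Without wild-type library 1 or G799R library 3 that median was −0.31 or −0.24, and without wild-type library 5 or G799R library 5 it was −0.08 or −0.10. Glomerular marker scaling lowered it to −0.75, with 23 genes lower and 0 higher by limma. The oxidative phosphorylation, fatty acid oxidation and bile acid lists then had 45, 30 and 12 members lower and 0 higher, with medians of −1.48, −1.52 and −2.13. Counts adjusted over the list alone were the same for these 4 lists and for both tubule lists. Proximal tubule markers were lower in the same libraries.

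**Figure D4:**
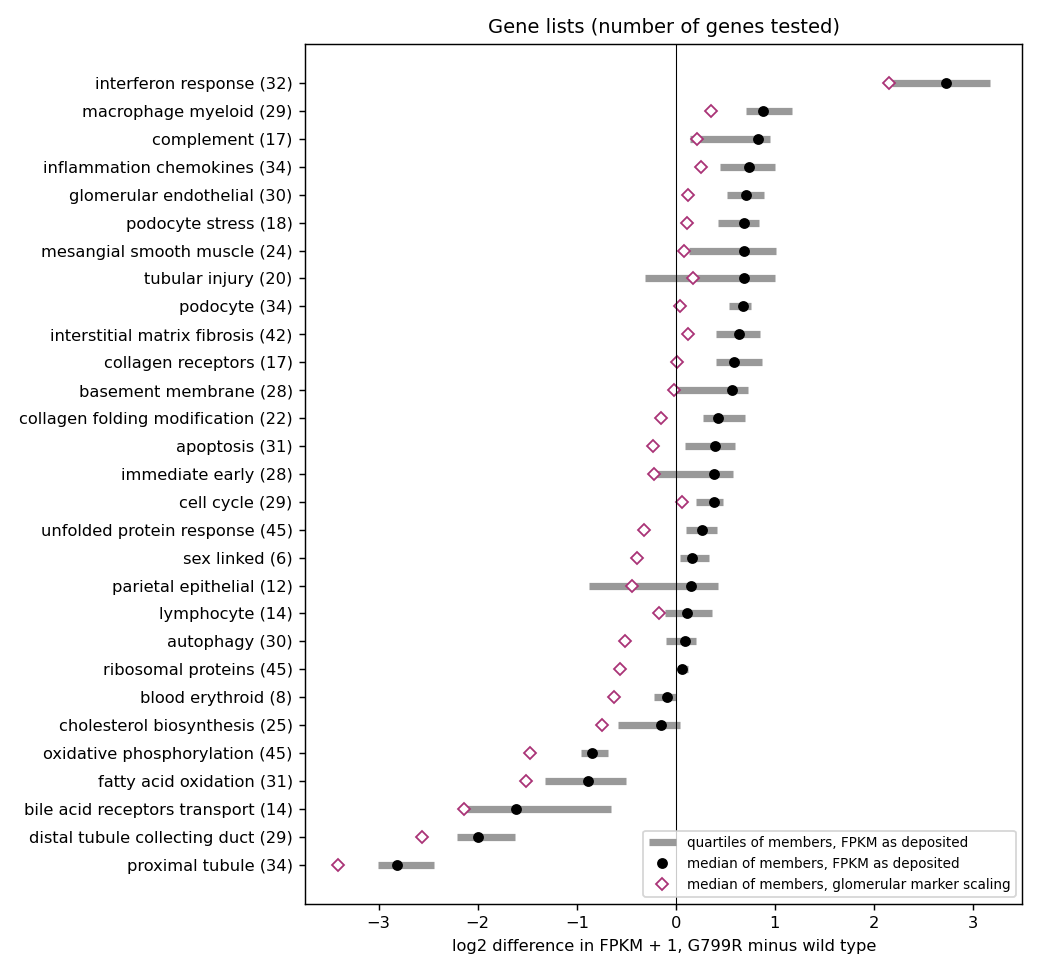
Median log2 difference (G799R minus wild type) of the members of 29 gene lists, with quartiles (grey bars), for FPKM as deposited (black) and under glomerular marker scaling (open diamonds). The interferon response median is 2.73 and 2.15, the proximal tubule median is −2.82 and −3.41, and the unfolded protein response median changes sign from 0.27 to −0.32. The median of all genes is 0.17 as deposited and −0.38 under glomerular marker scaling.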

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

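The tests of tubule, glomerular and interferon patterns in this part were chosen after the values were seen, and the counts of other splits were planned before. Of 286 groups of 5 values of named genes, 16 had 1 library far from the other 4 by Dixon's ratio, a gap above its 95% critical value, which chance gives in about 1 group in 20. Of 58 groups of list scores, 0 did.

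In wild type, library 5 stood above the others for the interferon genes Gbp2b (ratio 0.956, at 3.82 FPKM), Ifi44l (0.946) and Tgtp1 (0.718), and below them for Kdm5d (0.733). Wild-type library 1, which has the lowest tubule score of its group, was lowest for Cyp4a14 (0.795), Cyp4a10 (0.815) and Pax8 (0.720), and highest for Cd79a (0.756). In G799R, library 4 was highest for P3h3 (0.772) and lowest for Cd52 (0.885) and Cx3cl1 (0.751). Library 5 was highest for Cd59a (0.774) and lowest for Lamb2 (0.807). Library 1 was lowest for Cdkn1a (0.734), and library 3 was lowest for Pcna (0.816) and Kdm6a (0.776).

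The first pattern is the lower tubule score in G799R. A first test of fewer tubule fragments in the isolates, the within-group correlation of proximal with distal tubule scores, left it open (r = 0.49, permutation p = 0.19, rho = 0.47 with p = 0.21, r = 0.37 without the 2 farthest libraries). A second test, added after that result and after the library scores had been seen, found that tubule and glomerular scores went in opposite directions within groups (r = −0.70, permutation p = 0.0054, adjusted p = 0.0163 over 3 correlations, rho = −0.67 with p = 0.0235), consistent with a smaller tubule share of the RNA. Without the 2 farthest libraries r was −0.47 (permutation p = 0.0613), so the relation rests in part on them. A change in the tubule cells could not be tested apart from this, since the injury score gained 3.01 on the proximal tubule score (exact permutation p = 0.0079) and glomerular cells also express some injury genes, so isolate purity, tubule cells and genotype stay open.

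The second pattern is the rise of glomerular lists and of the unfolded protein response list. Less tubule RNA could raise the glomerular lists together, and among these no difference in rise was detected (endothelial minus podocyte −0.0276, exact permutation p = 0.83; mesangial minus podocyte −0.09, exact permutation p = 0.48). With the tubule score as a covariate, however, their medians parted, at 0.59 for podocyte, −0.44 for endothelial and −0.74 for mesangial. That score nearly follows genotype, so the fit is imprecise. The unfolded protein response score rose by 0.37 less than the glomerular score (difference −0.3699, exact permutation p = 0.0079). A smaller tubule share may account for its rise, but this difference cannot decide it. Such a share would raise genes that tubule cells also express by less than glomerular markers, and the size of that rise was not estimated. A common dilution by tubule RNA would need 41.0% of wild-type RNA to come from tubules, if all tubule RNA fell like the proximal list. That list had a median of −2.82, but the distal list only −2.00. Such a dilution would give a within-group slope of −0.70 for glomerular on tubule score, against −0.69 measured in wild type. In G799R the measured slope was −0.0758, where −0.0619 would follow. Each measured slope rests on 5 libraries and has no interval. The pooled score also averages unlike lists. In wild type the SD of the podocyte score was 0.10, against 0.31 for endothelial and 0.28 for mesangial, where a common dilution would move them alike. The closeness of the slopes is therefore weak evidence. A change by genotype within glomerular cells is not excluded.

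The third pattern is the interferon response. The tables argue against less tubule RNA as its whole cause, since its score rose by 2.04 more than the glomerular score (exact permutation p = 0.0079), and G799R libraries 3 and 4 do not carry it alone, since 32 members were called without them. Relative to the glomerular score, the interferon score was −1.56, −1.28, 0.40 and −0.12 in G799R libraries 1 to 4. In G799R library 5 it was −2.496, level with −2.499 in wild-type library 5, so its score showed no excess over that library. Wild-type library 5 was the highest of its group, and the others stood at −3.39 to −2.92. Single genes differed between these 2 libraries. Psmb8 was at 59.6 FPKM in G799R library 5 against 12.6 in wild-type library 5, but Isg15 at 8.97 against 7.52. More leukocytes could not be told apart from a response of other cells: within groups the interferon and myeloid scores had r = −0.32 (permutation p = 0.37, rho = −0.25 with p = 0.49, r = −0.30 without the 2 farthest libraries), and the interferon score rose 1.76 more than the myeloid score (exact permutation p = 0.0238). The 21 interferon genes looked up reached at most 0.155 FPKM, which leaves open whether interferon was made in the glomeruli, made elsewhere or made briefly. Genotype, infection, housing or strain may each underlie it, and none of these was tested.

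Among 100 of the 126 splits of the 10 libraries into groups of 5, only the real one, a count of 1, called 7845 genes, and the highest other split called 0. Every other split mixes the 2 groups, and their difference then widens the spread within its own groups. Few calls follow there in any case, so this count cannot decide about chance, nor tell genotype from isolate purity. For the lists, 12 of the 100 splits called at least 17, and the highest other split called 19. Chance is not excluded for the number of lists called. These splits also mix the 2 groups, however, so this count cannot decide about chance either.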

How the results depend on the processing

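Glomerular marker scaling and the leaving out of several libraries together were chosen after seeing the data, and the other alternatives before. Among alternatives other than glomerular marker scaling and the tubule covariate, no result changed direction except the ribosomal protein list, which was not called as deposited and had a median of −0.11 under median-of-ratios scaling. Sign changes where neither value was called were not counted as changes. The cause of each change below was not tested, except where the construction of the alternative shows it. Glomerular marker scaling divides the FPKM of every gene in a library by a factor set by the glomerular markers. Because of the pseudocount it lowers low genes less. The log2 difference went from 1.05 to 0.81 for Gzmb and from 0.63 to −0.0017 for Col4a3. The tubule score nearly follows genotype. Leaving out single libraries gave 6990 to 8169 called genes (4616 to 5587 higher, 2374 to 2582 lower) and 17 to 18 lists. The Col4a3 difference was then 0.59 to 0.67 and the tubule score difference −2.47 to −2.24. Medians ran from 0.53 to 0.62 for basement membrane, 2.34 to 3.06 for interferon response, 0.62 to 0.71 for podocyte, −2.92 to −2.62 for proximal tubule and 0.22 to 0.30 for the unfolded protein response. Unknown depth leaves low genes with no counting limit.

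The basement membrane list, not called as deposited, was called with no filter (median 0.54) and with a filter of 2 FPKM (0.61). It was also called under median-of-ratios scaling (0.40), without wild-type library 5 (0.58) and without G799R library 5 (0.58). Under glomerular marker scaling camera called it higher than other genes (median −0.0189, adjusted p = 2.8e-04). None of these calls held with an estimated correlation. The unfolded protein response list was no longer called under median-of-ratios scaling (0.0926; adjusted p = 0.0904), under quantile normalisation (0.19; adjusted p = 0.0537) or without wild-type library 1 and G799R libraries 3 and 4 (0.26; adjusted p = 0.0685). Median-of-ratios scaling gave 3057 higher and 3341 lower calls, and called 11 members of that list higher. Without G799R libraries 3 and 4, 7128 genes were called, and 7706 when wild-type library 1 was left out too.

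With the tubule score as a covariate 0 genes were called, 0 higher and 0 lower (707 at an unadjusted p under 0.05 by limma), and the Col4a3 call was lost (log2 difference 0.59, adjusted p = 0.92), in a fit whose median SE of the genotype term was 0.42 against 0.11 without the covariate. List medians that changed sign were glomerular endothelial −0.44, mesangial smooth muscle −0.74, distal tubule collecting duct 0.50, unfolded protein response −0.0613, collagen folding modification −0.0745, podocyte stress −0.23, cholesterol biosynthesis 0.33, bile acid receptors transport 0.02, ribosomal proteins −0.23. Of these, camera called the mesangial (adjusted p = 1.3e-04) and ribosomal protein (0.0011) lists lower and the distal tubule (0.0413) and cholesterol (0.0057) lists higher, and 12 lists were called in all, 0 with an estimated correlation. Lists that stayed called higher were podocyte (median 0.59, camera adjusted p = 5.7e-11) and interferon response (2.68, 3.5e-09). The inflammation and chemokine (0.91, 1.6e-05) and macrophage and myeloid (0.96, 0.0318) lists also stayed called higher. The complement list, not called as deposited, was called higher (0.73, 0.0076). Proximal tubule, oxidative phosphorylation and fatty acid oxidation lists stayed called lower. Genes that changed sign, none of them called, were Col4a2 −0.10, Cyp4a14 1.62, Hpd 1.48, Hspa5 −0.89, Xbp1 −0.0621, Serpine2 −0.20, Notch3 −0.11, Krt8 0.0965, Casp12 −0.16, Mbtps1 −0.0572, Sec61a1 −0.0613, P3h3 −0.49, Col5a1 −0.48, Spp1 0.68, Bid 0.32, Pcna −0.39, Mvd 0.24, Abcc2 0.11, Vdr 0.0639, Gadd45b −0.34, Klf6 −0.32, Rps27 −0.44, Rps16 −0.42, Rpl37 −0.59, Rps24 −0.0874, Kdm6a −0.30, Kdm5d −0.12.

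Under glomerular marker scaling 628 genes were called higher and 8027 lower, and 1580 genes were called in the direction opposite to that as deposited. List medians that changed sign were lymphocyte −0.17, unfolded protein response −0.32, collagen folding modification −0.15, basement membrane −0.0189, autophagy −0.52, immediate early −0.22, ribosomal proteins −0.56. The Col4a3 difference was −0.0017, and log2 differences that changed sign were Col4a4 −0.0852, Col4a5 −0.0782, Hspa5 −0.11, Ddit3 −0.23, Atf4 −0.51, Xbp1 −0.19, Mbtps1 −0.18, Sec61a1 −0.29, Lamb2 −0.0312, Cd151 −0.0447, Optn −0.0935, Rrm1 −0.20, Mcm3 −0.0137, Pcna −0.22, E2f1 −0.16, Klf6 −0.0381, Rps27 −0.34, Rps16 −0.41, Rpl37 −0.31, Rps24 −0.42, Ddx3y −0.0363, Kdm6a −0.25, Kdm5d −0.24.

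The replicate numbers shared by both groups did not pair the libraries: same-numbered libraries had correlations of −0.08 to 0.05 between their deviations from the group means, and 0 matched best with their own number. With the number as a replicate block 7388 genes were called (4937 higher, 2451 lower) and the same number of lists, 17. For the tubule score the replicate block gave the same difference of −2.35 with an exact sign-flip p of 0.0625, the smallest that 5 pairs allow.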

Other observations

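Several other gene groups had members that rose and members that fell in FPKM as deposited. Of 31 apoptosis genes 18 rose and 3 fell as deposited, while 2 were higher and 13 lower under glomerular marker scaling, and the list was not called (adjusted p = 0.17). The 3 that fell were Aifm1 (from 36.1 to 16.4 FPKM), Cycs (2.51-fold lower) and Bid (6.34-fold lower), of which Aifm1 and Cycs encode mitochondrial proteins. Of 30 autophagy genes 9 rose and 6 fell (9 and 5 adjusted over the list alone) as deposited, while 0 were higher and 26 lower under glomerular marker scaling by limma, with Optn 1.45-fold higher as deposited (log2 difference −0.09 under glomerular marker scaling) and Bnip3 2.15-fold lower (adjusted p of the list 0.72). Of 20 tubular injury genes 11 rose and 5 fell (12 and 5 adjusted over the list alone), against 6 higher and 6 lower under glomerular marker scaling. Cp, which encodes ceruloplasmin, was 4.56-fold higher, while Havcr1, the gene of kidney injury molecule 1, stood at 0.0896 ± 0.0822 FPKM against 1.04 ± 0.24 in wild type, and the list was not called (adjusted p = 0.69). Of 12 genes of parietal epithelium 3 rose and 4 fell (0 higher and 6 lower under glomerular marker scaling by limma), with Krt8 4.62-fold lower and Pax8 3.36-fold lower (adjusted p of the list 0.28). The tubule score was lower in the same G799R libraries.

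The remaining lists were not called as deposited either. Of 28 immediate early genes 13 rose and 1 fell (12 and 0 adjusted over the list alone; adjusted p of the list 0.40), while 1 was higher and 10 lower under glomerular marker scaling, with Atf3 2.30-fold higher. Of 29 cell cycle genes 5 rose (0 adjusted over the list alone; adjusted p of the list 0.59), against 0 higher and 1 lower under glomerular marker scaling by limma. Of 45 ribosomal protein genes 4 rose (0 adjusted over the list alone), with a median log2 difference of 0.07 that turned to −0.56 under glomerular marker scaling, where all 45 were lower (adjusted p of the list as deposited 0.92). Of 6 sex-linked genes 3 rose (adjusted p 0.66), against 0 higher and 4 lower under glomerular marker scaling by limma. Of 8 blood erythroid genes 1 fell, Hbb-bt at 8.72-fold lower, with a list median of −0.09 and an adjusted p of 0.17. The list was called when wild-type library 2 was left out (median −0.35), but not with an estimated correlation, and without wild-type library 4 its median was 0.20. Under glomerular marker scaling the medians of the autophagy, immediate early, apoptosis, parietal and sex-linked lists turned to −0.52, −0.22, −0.23, −0.44 and −0.39. Under that scaling the median of all genes was −0.38. Camera there called the cell cycle (adjusted p = 2.5e-05), immediate early (0.0099) and tubular injury (4.5e-05) lists higher than other genes. It called the ribosomal protein (7.4e-04) and autophagy (0.0112) lists lower, and no call held with an estimated correlation. The scaling lowers low genes less than high ones. The cell cycle list, with a wild-type score of 1.39, went from a median of 0.38 to 0.06. The ribosomal protein list, with a wild-type score of 7.03, went from 0.07 to −0.56. How far these calls follow from expression level was not tested. The median and the direction camera gave differed in sign for the autophagy (median 0.09), lymphocyte (0.11) and parietal epithelium (0.16) lists. Counts adjusted over the list alone were the same for apoptosis, parietal, lymphocyte, complement, sex-linked and blood erythroid genes.

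The following 3 tests were chosen after the values were seen. A candidate explanation for the higher Col4a1 and Col4a2 is a rise of all type IV collagen chains alike, but their mean rose by 0.97 more on the log2 scale than that of Col4a3, Col4a4 and Col4a5 (exact permutation p = 0.0159), a ratio on which scaling between libraries has little bearing. The rise also exceeded the endothelial and mesangial scores by 0.93 (exact permutation p = 0.0159). The mesangial list pools smooth muscle genes, however, and its members rose unequally (quartiles of the log2 difference 0.13 and 1.01). More mesangial RNA is therefore not excluded. A change in Col4a1 and Col4a2 expression is a hypothesis only, since cause and genotype were not separated. For 12 chaperones of the endoplasmic reticulum the score rose by 0.45 (exact permutation p = 0.0159), and relative to the glomerular score the difference was −0.18 (exact permutation p = 0.25), so a rise beyond that of glomerular markers was not shown.

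Trim12a and Trim34b, neighbouring paralogs on chromosome 7 that fall outside the naming rule and were chosen after their values were seen, moved in opposite directions. Trim12a was at 13.2 ± 3.25 FPKM in wild type and 0.435 ± 0.344 in G799R, and Trim34b at 0.409 ± 0.550 and 11.2 ± 4.98 (n = 5 each). Shared reads between the paralogs make both values uncertain. Why they moved in opposite directions was not tested, and the strain of the mice is not given.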
